A study of Mus musculus with 33 samples.

How the data were processed

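Gene expression was measured by RNA sequencing in 33 subcutaneous tumours grown from Myc-CaP cells, a mouse prostate cancer line driven by MYC. Per the labels, the cells were injected into both flanks of male FVB mice and treatment began at a tumour volume of 50 mm3. ESK981, an oral multi-kinase inhibitor that also inhibits the lipid kinase PIKfyve, was dosed at 15 mg/kg on 5 days of each week. An antibody against PD-1 or its isotype control was injected into the peritoneum 3 times a week at 200 µg per mouse. Tumours were taken after 3 weeks, and libraries were made from total RNA after ribosomal RNA depletion and sequenced on an Illumina HiSeq instrument.

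Per the labels, the tumours fell into 4 groups of 5 mice each: vehicle (10 tumours), ESK981 (8), ESK981 with anti-PD-1, called the combination here (8), and anti-PD-1 (7). The ear tag and flank in the labels gave the mouse of each tumour, and 13 mice had 2 tumours and 7 had 1. Tumours are named here by a mouse number from 1 to 5 within the group, given in the order of the labels, and by flank (L or R). These numbers pair nothing across groups.

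The deposited table held FPKM (fragments per kilobase of exon and 1e+06 fragments) for 48795 genes, made by the authors from reads aligned with STAR and counted with featureCounts on genome build mm10, per the submitters' processing notes. The versions of these tools, the gene annotation and the use of strand in counting are not given in the sources used here. Reads of overlapping genes, antisense genes, pseudogenes and near-identical copies (histones, ribosomal protein pseudogenes, small noncoding RNAs, the nuclear copies of mitochondrial genes) are therefore uncertain. All value columns matched a sample (0 unmatched). Gene identifiers with their version matched GENCODE M21 for 41341 genes, and 48349 matched in any version. Coordinates are those of M21 on GRCm38, and 132 symbols occurred more than once and were kept apart by identifier.

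Low FPKM values, multiplied by the union exon length of the gene, came out as whole multiples of 1 fragment in every tumour (100% of values, within 0.01), which gave the number of fragments per tumour. It ranged from 9.90e+06 in vehicle tumour 5R to 3.24e+07 in ESK981 tumour 1R. FPKM depend on the total, so no count model was fitted. Fragments on Gm23935, Gm26917 and Gm42418, which lie on ribosomal RNA sequence, were summed as ribosomal-RNA-like FPKM, and the FPKM of the 13 mitochondrially encoded protein genes were summed likewise.

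The mouse was the replicate. The values log2(FPKM + 0.5) were averaged over the tumours of a mouse, giving 20 mouse means, for the 15846 genes with an FPKM of at least 0.5 in at least 5 tumours, of which 11639 were protein-coding. Fold changes are therefore on the log2(FPKM + 0.5) scale, which understates the change of low genes. A linear model with the 4 groups was fitted in limma with a mean-variance trend (16 residual and 5.07 prior degrees of freedom), with two-sided tests and Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The comparisons were each treated group against vehicle, the combination against each single treatment, and the interaction, which is the ESK981 difference with anti-PD-1 minus that without it. Levels are given as the mean ± SD of FPKM over 5 mice, and log2 fold changes as the estimate ± SE.

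Of 42 gene lists fixed with 649 entries (immune and stromal cell types, interferon and antigen presentation, autophagy, lysosome and metabolism, stress, proliferation, tumour cell identity, other tissues and RNA quality), 41 had at least 3 members tested. The neuroendocrine list had 2 and was not tested. Each list was tested with the directional p of fry (limma), adjusted over the lists. This asks whether the members moved on balance one way and does not compare them with other genes. List effects are the mean log2 fold change over the members tested, with an SE from the list means of the mice. As alternatives, camera was run with an estimated correlation between genes and with the preset correlation of 0.01. Unlike fry, camera asks whether the members moved more than other genes, so the 2 tests answer different questions.

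The genes named were set by a rule. It took up to 8 called genes with the largest rise and up to 8 with the largest fall, with a mean log2 value of at least 1 in the higher group, no overlap between the mice of the groups and a symbol that is not a predicted or clone name of the forms Gm or AC, AL, BC, AI, AA or AU plus digits, Rik or an Ensembl ID. It added up to 4 members with the smallest adjusted p from each list that passed, and 18 genes whatever their result: Cxcl9, Cxcl10, Cd3e, Cd8a, Gzmb, Ifng, Pdcd1, Cd274, Kdr, Pecam1, Pikfyve, Map1lc3b, Sqstm1, Gpnmb, Mki67 and Myc, with 2 more that, like 1 of the lists, are not reported here. For the interaction it took up to 5 called genes of each sign. Any other gene is said to have been chosen after its values were seen.

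The groups, tests, lists, gene rule and a set of alternatives were fixed before the data were examined. Those alternatives were pseudocounts of 0.1 and 1, no filter and a filter at FPKM 1, median-of-ratios scaling, quantile normalization, tumours with the mouse as a random effect (estimated correlation 0.235), the same with flow cell as a term, array weights, no mean-variance trend, only the groups compared, and leaving out each mouse. Chosen after the data were seen were fits without vehicle 5R, anti-PD-1 4R and combination 5R, without ESK981 1R and 2R, without combination 1L, and protein-coding genes scaled to equal sums. The flow cell was read from the sample descriptions: 9 vehicle tumours were on 1 flow cell, and the remaining vehicle tumour (5R) was on the other with all 23 treated tumours.

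The gene fit was tested on simulated mouse means for ESK981 against vehicle with the same 15846 genes. It recovered 35 of 50 genes changed by 1 on the log2 scale, 45 of 50 at 1.5 and all 50 at 2 and at 3, with 9 unchanged genes called. The simulated values were independent noise for each gene and mouse. The filter, the averaging of tumours, flow cell and correlation between genes were therefore not tested. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.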

Results

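Subcutaneous Myc-CaP tumours were profiled after 3 weeks of vehicle, ESK981, anti-PD-1 or both agents together. The series concerns inhibition of autophagy through PIKfyve, the lipid kinase that ESK981 also inhibits, and its use with checkpoint blockade in prostate cancer. The 33 tumours came from 20 mice, 5 per group, and the comparisons ask what each treatment changed in the tumour transcriptome and whether the effect of ESK981 differed when anti-PD-1 was given. All means of FPKM below are over 5 mice per group with their SD, fold changes are on the log2(FPKM + 0.5) scale, and a gene is said to have risen or fallen only at a limma adjusted p under 0.05.

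Sequencing depth differed between the groups. It spanned 9.90e+06 to 1.84e+07 fragments in vehicle tumours, 1.81e+07 to 3.24e+07 in ESK981 tumours, 1.78e+07 to 2.48e+07 in combination tumours and 1.13e+07 to 2.42e+07 in anti-PD-1 tumours. Residual ribosomal RNA differed in the other direction. The ribosomal-RNA-like FPKM ran from 127087 to 240279 in vehicle tumours, from 15043 to 86387 with ESK981, from 19591 to 500377 with the combination and from 36276 to 179159 with anti-PD-1. Vehicle tumour 5R and anti-PD-1 tumour 4R had the lowest depths (9.90e+06 and 1.13e+07) and the most mitochondrial coding RNA (FPKM of 90856 and 52728), and combination tumour 5R had the most ribosomal RNA. Of the 10 vehicle tumours, 9 were sequenced on a flow cell of their own, and vehicle 5R shared the other with all 23 treated tumours. Genes with few fragments were therefore measured least precisely in vehicle tumours.

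ESK981 alone lowered lists of interferon gamma, antigen presentation, T cell and myeloid genes by the directional test of fry. None of these lists passed camera with an estimated correlation between genes (adjusted p = 0.178 or more), which compares the members with other genes. Camera with the preset correlation is given with the alternatives below. Many single genes were called, and several lists had the opposite sign in a fit with a flow cell term. All 20 tested genes of the interferon gamma response fell against vehicle (mean log2 fold change −1.56 ± 0.38, n = 5 mice per group), as did 8 of 10 genes of MHC class I presentation (−1.32 ± 0.32) and 8 of 9 of MHC class II presentation (−1.43 ± 0.34). The ligand of PD-1, Cd274 (chromosome 19, 29367455 to 29388095, plus strand), fell from 9.65 ± 4.23 to 1.93 ± 0.686 FPKM, 3.78-fold (log2 fold change −1.92 ± 0.39, adjusted p = 0.00545). The inducible nitric oxide synthase Nos2 fell from 16.4 ± 5.70 to 1.96 ± 1.10 FPKM, 7.35-fold (−2.88 ± 0.46, adjusted p = 0.00151; chromosome 11, 78920787 to 78960254). Among transcripts that rose were the urea cycle enzyme Cps1 and the insulin-like growth factor binding proteins Igfbp5 and Igfbp3.

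Over all genes, limma called 2278 of 15846 against vehicle, 1418 higher and 860 lower, of which 1564 were protein-coding (889 higher, 675 lower). The remainder were 145 pseudogenes, 169 small noncoding RNAs and 400 other noncoding genes, and 370 of the last class were higher. The median of all log2 fold changes was 0.11. Median-of-ratios scaling moved it to 0.01 and called 2213 higher and 2208 lower.

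Lists of cytotoxic and T cell genes were lower in ESK981 tumours (fry adjusted p = 0.00742 and 0.0173, and adjusted p = 0.178 and 0.192 with an estimated correlation). With a flow cell term, which rests on vehicle 5R, they were at 0.14 and 0.38 (adjusted p = 0.849 and 0.549). Inhibitory receptors were at 0.37 there (0.549), and all 3 lists thus had the opposite direction. The T cell list also did not pass without ESK981 1R and 2R (−0.66, fry adjusted p = 0.0552) or without vehicle mouse 3 (−0.65, 0.0529). In the list of CD8 T cells and cytotoxic effectors (−1.15 ± 0.28), 5 of 9 genes fell over all genes tested and 8 when adjusted over the list alone. The T cell chemokine Ccl5 fell from 18.9 ± 7.53 to 2.37 ± 1.19 FPKM (5.54-fold, adjusted p = 0.00193). The effector molecules Gzmb (2.77-fold, from 1.94 ± 0.516 to 0.315 ± 0.167 FPKM), Prf1 (2.69-fold) and Nkg7 (2.91-fold) fell as well. Among 14 T cell genes (−0.73 ± 0.22), 9 fell, 12 when adjusted over the list alone, including the receptor chains Cd3g (2.23-fold) and Cd3e (2.08-fold), Trbc2 (2.23-fold) and the kinase Lck (1.90-fold). Of 5 inhibitory receptors (−0.74 ± 0.21), Lag3 (2.13-fold), Pdcd1 (1.90-fold) and Ctla4 (1.61-fold) fell and 4 passed when adjusted over the list alone, while Havcr2 was at −0.74 ± 0.27 (adjusted p = 0.0711). Ifng fell 2.04-fold, and Cd8a was at −0.66 ± 0.23 (adjusted p = 0.057). Several of these genes lay near 1 FPKM or below in vehicle tumours. The lists of regulatory T cells (−0.03 ± 0.14, 1 of 4 higher and 1 lower), NK cells (−0.41 ± 0.19) and B and plasma cells (−0.05 ± 0.42) had adjusted p of 0.983, 0.106 and 0.603.

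Of the 6 myeloid lists 5 passed fry, though not with an estimated correlation (adjusted p = 0.178 to 0.251), and mast cells did not. The macrophage list passed in 13 of 23 settings, leaving out single mice included, and the neutrophil list in 14 of 23. With the flow cell term none of the 5 passed and dendritic cells were at 0.23 (adjusted p = 0.81), the opposite direction. Without ESK981 1R and 2R the dendritic cell list was at −0.56 and did not pass (fry adjusted p = 0.0552). Of 8 genes of alternatively activated macrophages (−1.24 ± 0.33), Retnla (5.76-fold), Il4ra (2.65-fold), Clec10a (2.53-fold) and Arg1 (1.74-fold, from 127 ± 20.6 to 70.3 ± 6.08 FPKM) fell, and 7 passed when adjusted over the list alone. Of 9 inflammatory myeloid genes (−0.89 ± 0.22), 5 fell and 8 when adjusted over the list alone, among them Nos2, the cytokine Il1b, the costimulatory ligand Cd80 and the inflammasome sensor Nlrp3. Of 14 macrophage genes (−0.76 ± 0.28), Cd68 (1.80-fold), C1qa (2.04-fold), Trem2 (1.76-fold), Msr1 (1.95-fold) and 1 other fell, and 10 when adjusted over the list alone. Of 6 neutrophil genes (−0.73 ± 0.26), Clec4d (2.92-fold) and Csf3r (1.95-fold) fell, 4 when adjusted over the list alone. Of 3 genes of dendritic cells (−0.68 ± 0.20), Batf3 and Irf8 fell, and all 3 when adjusted over the list alone. Mast cell genes were at −0.63 ± 0.45 (adjusted p = 0.338).

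Within the interferon gamma list, the guanylate binding protein Gbp2 fell from 44.3 ± 15.7 to 10.2 ± 5.07 FPKM (4.18-fold), and Irf1, Psmb10 and Socs1 fell 2.92-, 2.90- and 3.56-fold. The T cell attracting chemokines Cxcl9 (14.2 ± 5.23 to 5.07 ± 2.12 FPKM, 2.58-fold, adjusted p = 0.0246) and Cxcl10 (2.16-fold) fell. All 20 genes also passed when adjusted over the list alone. The immunoproteasome subunits Psmb8 (3.54-fold) and Psmb9 (4.18-fold) and the peptide transporter subunits Tap1 (3.33-fold) and Tap2 (2.57-fold) fell among the class I genes, 8 of 10 when adjusted over the list alone. Among class II genes, H2-Ab1 (85.9 ± 27.8 to 21.5 ± 7.20 FPKM, 3.62-fold), H2-DMa (3.17-fold), H2-Eb1 (2.48-fold) and H2-DMb2 (2.51-fold) fell, 9 of 9 when adjusted over the list alone. The type I interferon list did not pass (−0.12 ± 0.16, adjusted p = 0.653), with 4 of 22 genes lower. Adjusted over the list alone, 2 were higher and 4 lower. For change in either direction the fry adjusted p of this list was 0.0355. Of 12 other chemokines (−0.91 ± 0.21), 6 fell, including Ccl4 (4.15-fold), Ccl2 (3.21-fold), Ccl3 (3.20-fold) and Ccl7 (2.90-fold), and 9 fell and 1 rose when adjusted over the list alone. Of 10 immediate early genes (−0.60 ± 0.11), Fos (2.44-fold), Dusp1 (1.64-fold), Fosb, Zfp36 and 1 other fell, 7 when adjusted over the list alone.

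These 13 lists passed the directional test of fry with adjusted p of 0.00269 for immediate early genes, 0.00742 for CD8, interferon gamma, MHC class I, MHC class II and chemokine genes, 0.00962 for alternatively activated and inflammatory myeloid genes, 0.00969 for dendritic cells, 0.0104 for inhibitory receptors, 0.0173 for T cells, 0.0278 for neutrophils and 0.0457 for macrophages. None of these calls held with camera and an estimated correlation. There the adjusted p = 0.178 with an estimated correlation for the 8 lists with a fry adjusted p up to 0.00962, 0.179 for inhibitory receptors, 0.190 for dendritic cells and neutrophils, 0.192 for T cells and 0.251 for macrophages. The 13 mitochondrially encoded transcripts, taken as a measure of RNA quality, fell with them (−1.63 ± 0.34, 12 called and all 13 when adjusted over the list alone, adjusted p = 0.00534, and adjusted p = 0.178 with an estimated correlation). Among these were mt-Nd6 (10.9-fold), mt-Co2 (4.52-fold), mt-Nd4l (3.31-fold) and mt-Nd3 (3.22-fold).

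**Figure D1:**
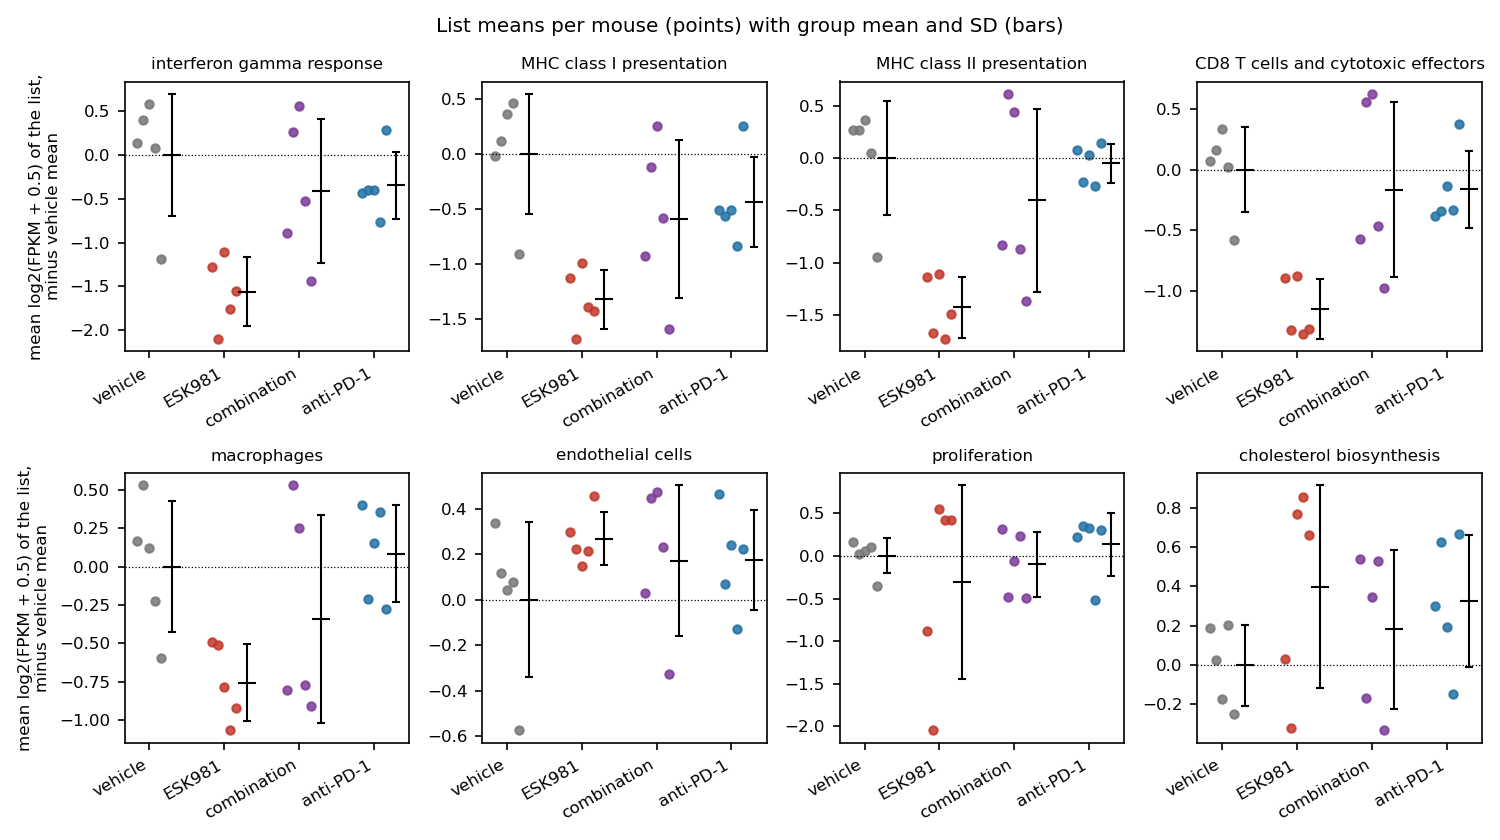
Scores of 8 gene lists per mouse, as the list mean of log2(FPKM + 0.5) minus the vehicle mean, with points for the 5 mice of each group and bars for the group mean and SD. The ESK981 mice lie at a mean of −1.56 in the interferon gamma list, and vehicle mouse 5 at −1.19.

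Transcripts that rose with ESK981 included Cps1 (chromosome 1, 67123026 to 67231259), from 1.16 ± 0.619 to 5.54 ± 2.60 FPKM (3.72-fold, log2 fold change 1.90 ± 0.31, adjusted p = 0.00162). Igfbp5 rose from 78.7 ± 40.5 to 328 ± 225 FPKM (1.89 ± 0.34, adjusted p = 0.00306) and Igfbp3 from 6.80 ± 3.00 to 17.4 ± 4.86 FPKM (2.67-fold, adjusted p = 0.00396). Small RNAs made up the rest of the largest rises and nearly all of the largest falls. Snord59a, Snord73a, Mir6920, Mir1898 and Snord70 rose 2.88- to 4.07-fold. Vaultrc5 fell 18.7-fold, the 7SL genes Rn7s1, Rn7s2 and Rn7s6 by 16.2-, 14.3- and 9.58-fold, Snord17 12.7-fold, Scarna17 9.98-fold and the ribosomal RNA gene copy Rn18s-rs5 8.83-fold, in groups that differed in ribosomal RNA carry-over. Reads of such multicopy genes are uncertain. Vaultrc5, Rn7s1, Rn7s2, Snord17 and Scarna17 were lower in every treated group, so a batch of the vehicle libraries is not separated from treatment for them.

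Vascular, stromal, tumour cell and metabolic lists did not pass against vehicle. Endothelial genes were at 0.27 ± 0.17 (4 of 14 higher, adjusted p = 0.249), angiogenic tip genes at 0.27 ± 0.16 (1 of 11 higher, 0.213), pericyte and smooth muscle genes at −0.03 ± 0.25 (2 of 10 higher, 1 lower, 0.983) and fibroblast and matrix genes at −0.82 ± 0.31 (6 of 14 lower, 8 when adjusted over the list alone, 0.0789). The kinase receptor Kdr was at 0.44 ± 0.19 (adjusted p = 0.113) and Pecam1 at 0.35 ± 0.26 (0.357). Of 31 autophagy genes, 4 rose (list 0.18 ± 0.10, adjusted p = 0.218), with Map1lc3b at 0.40 ± 0.16 (0.0952), Sqstm1 at 0.20 ± 0.15 (0.389) and Pikfyve at 0.22 ± 0.17 (0.397). Lysosome genes were at −0.11 ± 0.16 (1 of 32 higher, 2 lower, 0.698), with Gpnmb at −0.36 ± 0.26 (0.365). Cholesterol biosynthesis was at 0.40 ± 0.24 (0 of 22 called, 0.222). The epithelial list was at 0.05 ± 0.18 (1 of 10 higher, 0.662). Proliferation genes were at −0.31 ± 0.40 (1 of 29 lower, 0.603), with ESK981 mice 1 and 2 at −0.88 and −2.05 and the other 3 between 0.42 and 0.55, so the sign of the mean rests on 2 mice. Mki67 averaged 17.7 ± 3.18 FPKM with vehicle and 21.4 ± 12.4 with ESK981, with a log2 fold change of −0.21 ± 0.45, so the differences of its means on the 2 scales have opposite signs, and without ESK981 1R and 2R it was at 0.74 (adjusted p = 0.0414).

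Further lists gave, in the same comparison, 0.11 ± 0.22 for MYC-driven ribosome biogenesis (adjusted p = 0.698; Myc itself −0.15 ± 0.21), 0.15 ± 0.17 for oxidative phosphorylation (0.603), −0.15 ± 0.18 for hypoxia (0.603), 0.25 ± 0.21 for the integrated stress response (0.418) and 0.33 ± 0.15 for the unfolded protein response (0.111). Of 12 p53 targets, 3 rose and 1 fell (0.02 ± 0.11, directional adjusted p = 0.930, and 0.0191 for change in either direction). Markers of other tissues were at −0.55 ± 0.75 for skeletal muscle (0.603), 0.10 ± 0.30 for adipocytes (0.645), 0.01 ± 0.17 for skin keratinocytes (0.983) and 1.09 ± 0.41 for red blood cells (1 of 3 higher, 2 when adjusted over the list alone, 0.0513). The histone list was at −0.68 ± 0.42 (0.275) and ribosomal protein genes at 0.11 ± 0.16 (0.645). The mean, the median and the test differed in sign for regulatory T cells, B and plasma cells, pericytes, type I interferon, adipocytes and keratinocytes.

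In a fit of single tumours with flow cell as a term, the flow cell effect rests on vehicle 5R alone. That fit called 5786 genes (5554 higher, 232 lower). The interferon gamma list was at 0.25 (adjusted p = 0.849) and MHC class I at 0.08 (adjusted p = 0.878), the opposite direction. MHC class II (−0.11, fry adjusted p = 0.858), other chemokines (−0.47, 0.549) and immediate early genes (−0.53, 0.203) stayed below 0 but did not pass. The count of 2278 was 1390 without ESK981 1R and 2R, and 1054, 1200, 1153, 1323, 1168 and 1220 without vehicle mouse 2 or 3 or ESK981 mouse 1, 2, 4 or 5.

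**Figure D2:**
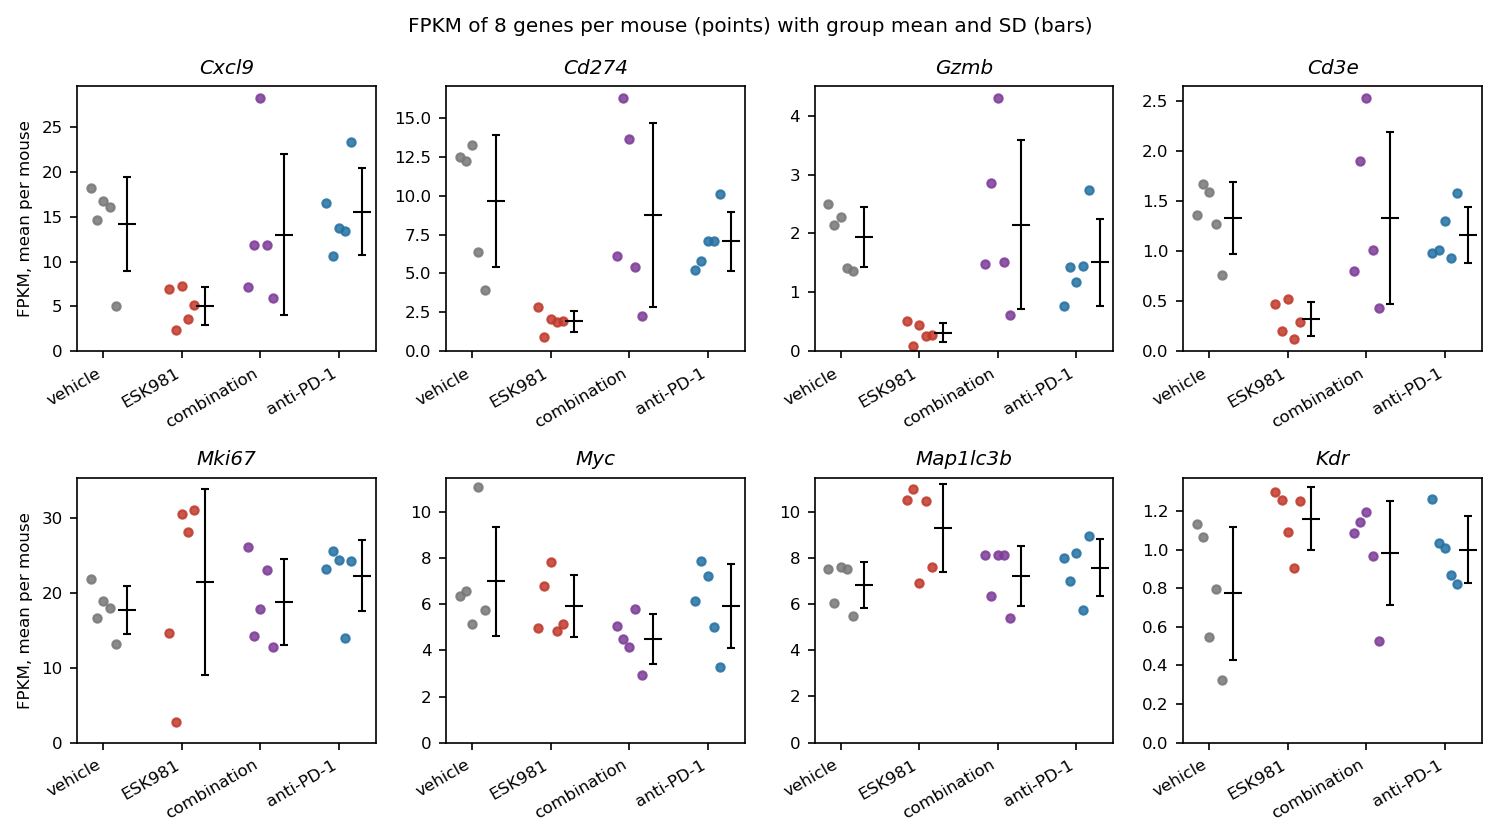
FPKM of Cxcl9, Cd274, Gzmb, Cd3e, Mki67, Myc, Map1lc3b and Kdr in each mouse, with the group mean and SD. Cd274 averaged 9.65 FPKM with vehicle, 1.93 with ESK981, 8.76 with the combination and 7.07 with anti-PD-1.

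Few transcripts differed between anti-PD-1 and vehicle tumours, and no immune gene list passed. The hypoxia-inducible factor subunit Hif3a rose from 5.47 ± 1.18 to 8.67 ± 0.281 FPKM (1.59-fold, log2 fold change 0.67 ± 0.14, adjusted p = 0.0241). The pseudogenes Rpl10-ps6 (2.18-fold) and Rps6-ps4 (1.74-fold), RP23-478A9.6 (3.23-fold) and RP24-545I11.1 (2.06-fold), with clone names of a form the naming rule did not list, and Mir697 (2.07-fold) also rose. Small noncoding RNAs fell: Snord17 9.69-fold, Vaultrc5 7.96-fold, Scarna17 7.21-fold, Rn7s2 6.60-fold, Snord15a 5.72-fold, Rn7s1 4.53-fold, Snora78 3.71-fold and Rprl3 3.40-fold. All of these small RNAs were lower, and Rps6-ps4 and Mir697 higher, in every treated group. A batch of the vehicle libraries is therefore not separated from treatment for them.

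Of the 124 genes called against vehicle, 75 were higher and 49 lower, and 12 were protein-coding (6 and 6), 66 pseudogenes (55 and 11) and 38 small noncoding RNAs (7 and 31). Median-of-ratios scaling called 124 higher and 234 lower. Chosen after their values were seen, Vtcn1, which encodes the checkpoint ligand B7-H4, rose 2.13-fold (adjusted p = 0.0401), and the zinc transporter Slc39a7 (2.19-fold, adjusted p = 0.000887; chromosome 17, 34028269 to 34031682), Cenpb (1.76-fold) and Ptms (1.80-fold) fell. Slc39a7, Cenpb and Ptms were lower in every treated group, so a vehicle batch is not separated from treatment for them. Among 41 lists, fry passed 0, with 0 at any camera correlation that was estimated and the smallest adjusted p at 0.749. The interferon gamma list was at −0.34 ± 0.38, CD8 and cytotoxic genes at −0.16 ± 0.28, T cells at −0.16 ± 0.22, MHC class I at −0.43 ± 0.32 and type I interferon at 0.25 ± 0.16, where 2 of 22 genes rose when adjusted over the list alone. Cxcl9 was at 0.22 ± 0.38, Cd274 at −0.23 ± 0.39, Gzmb at −0.29 ± 0.32 and Cd3e at −0.06 ± 0.27. The mitochondrially encoded genes were at −0.58 ± 0.34. The mean and median of the oxidative phosphorylation list differed in sign.

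With the flow cell term, 4397 genes were called against vehicle (4300 higher, 97 lower), and 1769 without vehicle 5R, anti-PD-1 4R and combination 5R. The 124 genes became 216, 49, 52, 69 and 53 without vehicle mouse 1, 2, 3, 4 or 5 and 29, 34, 37, 252 and 375 without anti-PD-1 mouse 1, 2, 3, 4 or 5.

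Many small RNAs were lower in combination than in vehicle tumours, and 1 of 41 lists passed. The 10 immediate early genes averaged −0.48 ± 0.11 (fry adjusted p = 0.0218, and adjusted p = 0.239 with an estimated correlation), a call made in 11 of 23 settings, and chance was not excluded by splits of the mice (10 of 100 gave as many lists, highest 14). Over all genes 0 of the 10 passed, and 8 did when adjusted over the list alone, with Dusp1 at −0.60 ± 0.16 (adjusted p = 0.103), Fos at −0.94 ± 0.27 (0.131), Fosb at −0.67 ± 0.21 (0.174) and Nr4a1 at −0.55 ± 0.20 (0.237). Vaultrc5 fell 13.7-fold, Snord17 9.57-fold, Scarna17 8.31-fold, Rn7s1 7.95-fold, Rn7s2 7.51-fold, Mir5099 7.35-fold, Snord15a 7.27-fold and mt-Nd6 6.27-fold. All of these but mt-Nd6 were lower in every treated group, so a batch of the vehicle libraries is not separated from treatment for them. Mir7061 (3.43-fold), Mir697 (2.003-fold) and Rps6-ps4 (1.90-fold) rose. Mir697 and Rps6-ps4 were higher in every treated group, so the same limit holds for them.

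Limma called 96 genes against vehicle, 13 higher and 83 lower, of which 23 were protein-coding (1 higher, 22 lower), 46 small noncoding RNAs and 21 pseudogenes. Median-of-ratios scaling called 537 higher and 511 lower. Chosen after their values were seen, the interferon-inducible Ifi27l2a fell from 11.2 ± 6.25 to 1.98 ± 0.556 FPKM (3.26-fold, adjusted p = 0.00855), and Slc39a7 (2.73-fold), Cenpb (2.23-fold), Ptms (2.11-fold) and Crip1 (2.17-fold) fell. Of these, Slc39a7, Cenpb and Ptms were lower in every treated group, so a vehicle batch is not separated from treatment for them. The interferon gamma list was at −0.41 ± 0.38 (20 of 20 genes below 0), MHC class I at −0.59 ± 0.32 (9 of 10), MHC class II at −0.40 ± 0.34 (9 of 9), CD8 and cytotoxic genes at −0.17 ± 0.28, T cells at −0.14 ± 0.22 and alternatively activated macrophages at −0.80 ± 0.33 (adjusted p = 0.402, 4 of 8 lower when adjusted over the list alone). Cxcl9 was at −0.18 ± 0.38, Cd274 at −0.26 ± 0.39, Gzmb at 0.00 ± 0.32, Cd3e at −0.02 ± 0.27 and Myc at −0.54 ± 0.21 (adjusted p = 0.296). The mitochondrially encoded genes were at −0.94 ± 0.34 (adjusted p = 0.402, 1 of 13 lower and 9 when adjusted over the list alone). Signs of mean, median and test differed for autophagy, epithelial, p53, keratinocyte and red blood cell lists.

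With the flow cell term 4467 genes were called (4278 higher, 189 lower), and 1461 without vehicle 5R, anti-PD-1 4R and combination 5R, where 0 lists passed. Without vehicle mouse 2 or combination mouse 2 or 5 the count was 62, 154 or 408, and the immediate early call was lost without vehicle mouse 2 or 4 or combination mouse 1, 4 or 5.

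Some genes were called against vehicle in more than 1 treatment. The same sign was called for 77 genes with ESK981 and anti-PD-1, 93 with ESK981 and the combination, 47 with anti-PD-1 and the combination, and 46 in all 3 groups. In 100 simulations the values of all mice, vehicle included, were drawn as independent noise around the mean of each gene. The mean overlaps were 0, 0, 0.01 and 0, where almost no gene was called at all. Such values carry no batch and no correlation between genes, so they do not show the overlap that these vehicle mice would give. Independent lists of these sizes would share 9.37, 5.67, 0.318 and 0.0194 genes, a value that leaves out the shared vehicle mice. With the vehicle mice split between the comparisons, a median of 14, 26 and 10 genes was shared over 10 splits, where independent lists of the sizes called there would share a median of 0.173, 0.3497 and 0.0208. Both parts of the vehicle mice still share any batch of their libraries. Of the 46 genes, 41 were lower in treated tumours, 28 were small noncoding RNAs, 13 pseudogenes and 5 protein-coding. They include Vaultrc5, Snord17, Scarna17, Rn7s1 and Rn7s2, but not Rn7s6 or Rn18s-rs5.

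**Figure D3:**
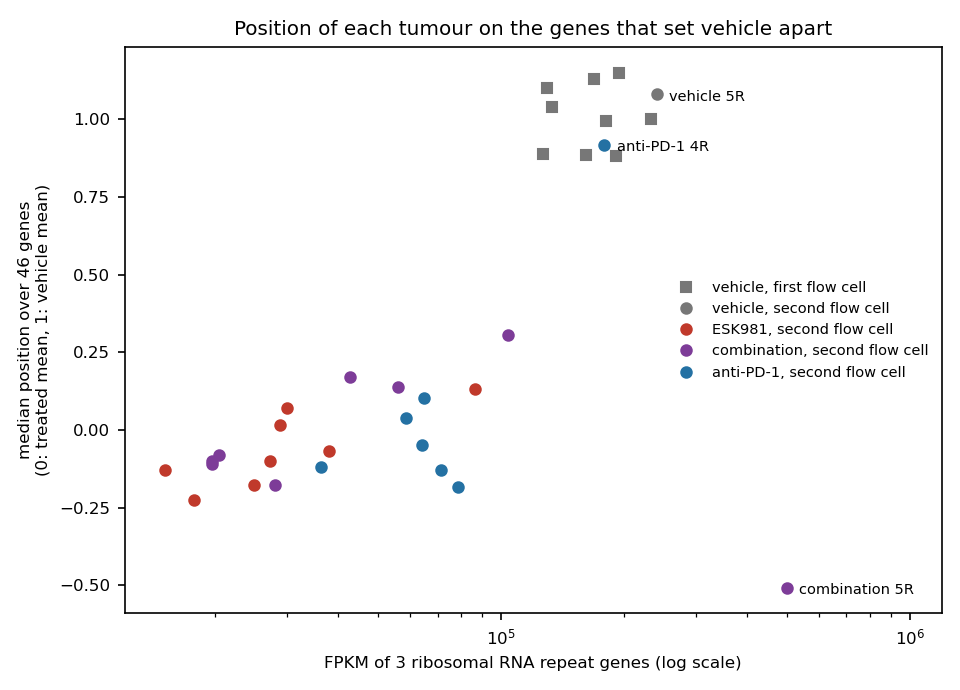
Ribosomal-RNA-like FPKM of each tumour (log axis) against its median position over the 46 genes called in all 3 treated groups, where 0 is the mean of the treated tumours and 1 that of the other vehicle tumours. Anti-PD-1 4R lies at 0.918 and vehicle 5R at 1.08, and combination 5R, with the most ribosomal RNA, lies at −0.508.

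Adding anti-PD-1 to ESK981 gave higher means of cytotoxic and interferon gamma genes, none of which passed over all genes. Lane largely followed group here: ESK981 tumours were on lanes 3 and 4, and combination tumours on lane 5, except combination 1L on lane 4. In the interferon gamma list combination 1L scored −1.85, and 1R of the same mouse, on lane 5, scored 0.06. Combination 5R, also on lane 5, scored −1.44. Lane is therefore not separated from treatment in this comparison. Cd274 averaged 1.93 ± 0.686 FPKM with ESK981 and 8.76 ± 5.93 with the combination (log2 fold change 1.66 ± 0.39, adjusted p = 0.325), Gzmb 0.315 ± 0.167 and 2.15 ± 1.44 (1.48 ± 0.32, 0.325), Cd3e 0.323 ± 0.170 and 1.34 ± 0.859 (1.04 ± 0.27, 0.325) and Cxcl9 5.07 ± 2.12 and 13.0 ± 8.96 (1.19 ± 0.38, 0.507). The interferon gamma list was at 1.15 ± 0.38, with 19 of 20 genes higher when adjusted over the list alone. CD8 and cytotoxic genes were at 0.98 ± 0.28 (8 of 9), MHC class II at 1.02 ± 0.34 (9 of 9), inflammatory myeloid genes at 0.78 ± 0.22 (8 of 9) and NK cells at 0.56 ± 0.19 (3 of 3), each with 0 genes over all genes tested.

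These 5 lists shared a fry adjusted p of 0.0738 and none of 41 passed. T cells were at 0.58 ± 0.22 (adjusted p = 0.11), chemokines at 0.59 ± 0.21 (0.11), MHC class I at 0.73 ± 0.32 (0.187), mitochondrially encoded genes at 0.69 ± 0.34 (0.208) and red blood cell genes at −1.03 ± 0.41 (0.11). The red blood cell scores of ESK981 1R and 2R (3.28 and 2.41) were the highest of their group. Limma called 0 of 15846 genes, with 1226 at an unadjusted p under 0.05 and a smallest adjusted p of 0.325. Chosen after their values were seen, Ccl5 was at 2.11 ± 0.42, Nos2 at 2.18 ± 0.46, Prf1 at 1.26 ± 0.30, Ccl2 at 1.41 ± 0.31, Igfbp5 at −1.43 ± 0.34 and Cps1 at −1.38 ± 0.31, all with an adjusted p of 0.325. Signs of mean, median and test differed for B cells, type I interferon, epithelial, keratinocyte and histone lists.

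Under median-of-ratios scaling 11 lists passed, all higher in the combination, with the interferon gamma list at 1.23 (adjusted p = 0.0166), and 11 passed without vehicle 5R, anti-PD-1 4R and combination 5R, where 41 genes were called. Without combination mouse 5 alone, 10 lists passed and the interferon gamma list was at 1.41 (adjusted p = 0.0171).

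Adding ESK981 to anti-PD-1 gave no call among single genes or lists, which does not show that nothing changed. Cd274 averaged 7.07 ± 1.89 FPKM with anti-PD-1 and 8.76 ± 5.93 with the combination (log2 fold change −0.03 ± 0.39, opposite in sign to the difference of the FPKM means), Cxcl9 15.6 ± 4.86 and 13.0 ± 8.96 (−0.39 ± 0.38), Gzmb 1.51 ± 0.739 and 2.15 ± 1.44 (0.29 ± 0.32) and Cd3e 1.16 ± 0.278 and 1.34 ± 0.859 (0.04 ± 0.27). The interferon gamma list was at −0.07 ± 0.38, type I interferon at −0.35 ± 0.16 (22 of 22 genes below 0, adjusted p = 0.952), MHC class II at −0.35 ± 0.34 (9 of 9), macrophages at −0.42 ± 0.28 (14 of 14) and hypoxia at −0.34 ± 0.18. Map1lc3b was at −0.07 ± 0.16, Pikfyve at 0.11 ± 0.17 and Myc at −0.35 ± 0.21 (adjusted p = 0.928). Irf7, chosen after its values were seen, was at −0.66 ± 0.20 (adjusted p = 0.528).

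Limma called 0 genes here, with 942 at an unadjusted p under 0.05 and a smallest adjusted p of 0.118, and fry passed 0 of 41 lists (smallest adjusted p 0.952). This pair of groups lies on a single flow cell, but no lane held tumours of both, so lane is not separated from treatment. Signs of mean, median and test differed for CD8, regulatory T, NK, endothelial, oxidative phosphorylation and p53 lists. Without anti-PD-1 mouse 5, 59 genes were called.

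The difference between the 2 effects of ESK981 was tested as an interaction. It called 4 of 15846 genes, all noncoding: Scarna17 (3.12 ± 0.47, adjusted p = 0.0219; chromosome 18, 74778391 to 74778469), Gm23547 (3.92 ± 0.69, 0.0482), Gm15466 (1.64 ± 0.29, 0.0482) and Gm23134 (−1.62 ± 0.28, 0.0482), with 2879 genes at an unadjusted p under 0.05. All 4 are among the 46 genes that set vehicle apart from every treated group, so the interaction there measures changes in all treated groups that did not add up. The count was 0 without vehicle mouse 4, ESK981 mouse 1, 4 or 5, combination mouse 3 or anti-PD-1 mouse 1, 2 or 3, and 12, 29, 35, 55 and 67 without ESK981 mouse 3, combination mouse 4 or 5 or anti-PD-1 mouse 4 or 5. Scarna17 averaged 136 ± 13.1 FPKM with vehicle, 13.8 ± 4.38 with ESK981, 23.9 ± 20.3 with anti-PD-1 and 18.2 ± 10.6 with the combination. The interferon gamma list differed by 1.49 ± 0.54 (17 of 20 genes higher when adjusted over the list alone, 0 over all genes), CD8 genes by 1.14 ± 0.40 (6 of 9), MHC class I by 1.16 ± 0.46 (8 of 10), inflammatory myeloid genes by 0.93 ± 0.31 (6 of 9) and mitochondrially encoded genes by 1.27 ± 0.48 (10 of 13). The smallest adjusted p over the 41 lists was 0.163, so the lower interferon gamma list with ESK981 alone was not shown to differ from its value on top of anti-PD-1. The list passed under median-of-ratios scaling (1.70, adjusted p = 0.013) and without vehicle 5R, anti-PD-1 4R and combination 5R (1.72, adjusted p = 0.00737), and was at −0.23 with the flow cell term (adjusted p = 0.811), the opposite direction. The median of all interaction log2 differences was −0.22, and mean and test of the regulatory T cell list differed in sign.

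Across 15846 genes, the log2 fold changes of ESK981 without and with anti-PD-1, which share no library, correlated with Pearson's r of 0.265 and Spearman's rho of 0.366 (0.382 for Pearson's r over protein-coding genes). Genes are not independent replicates, and the jackknife SE over mice was 0.305. Of the 2278 genes called against vehicle, 63.5% had the same sign in the combination minus anti-PD-1, where no gene was called. The genes that rose with ESK981 alone had a median there of −0.00 and those that fell a median of −0.20, beside −0.09 for all genes.

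**Figure D4:**
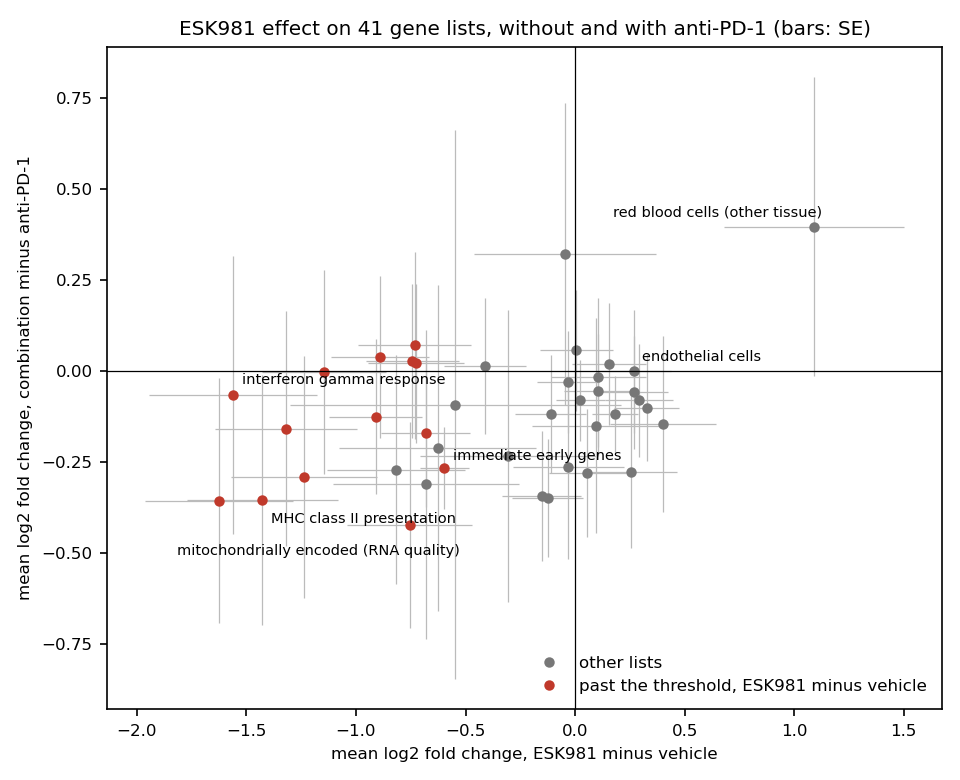
Mean log2 fold change of 41 lists for ESK981 minus vehicle (x axis) against combination minus anti-PD-1 (y axis), with SE as bars and lists past the threshold for ESK981 in red. The interferon gamma list lies at −1.56 on the x axis and −0.07 on the y axis.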

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

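The tests of flow cell, sequencing depth, a wrong label on anti-PD-1 4R, ribosomal RNA carry-over, the library batch of the vehicle tumours, fewer non-tumour cells and labels of a neighbouring mouse were chosen after the result was seen.

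Samples far from the others of their group were sought in 184 groups of values, and 25 were found, where chance alone marks about 1 in 20 groups (9.2 of 184). Vehicle 5R stood apart with mitochondrial coding FPKM of 90856 (group median 21346), nuclear protein-coding FPKM of 84450 (115716) and 9726 genes at FPKM 1 or more (11982). Its mouse, vehicle 5, was the lowest of its group in the lists of inhibitory receptors (score −0.61), dendritic cells (−0.49), interferon gamma (−1.19), MHC class II (−0.95), autophagy (−0.24) and proliferation (−0.36). Anti-PD-1 4R had 1.13e+07 fragments (group median 2.07e+07), ribosomal-RNA-like FPKM of 179159 (64908), mitochondrial FPKM of 52728 (7780) and 10505 genes at FPKM 1 or more (12342). Its mouse was the lowest of its group in proliferation (−0.51) and MYC-driven ribosome biogenesis (−0.58). Combination 5R had ribosomal-RNA-like FPKM of 500377 (group median 35436) and 10269 genes at FPKM 1 or more (12037), and its mouse was the lowest of its group in autophagy (−0.47) and p53 targets (−0.59). ESK981 3R had ribosomal-RNA-like FPKM of 86387 (28041). Markers of other tissues stood out within their groups in combination mouse 3 (skeletal muscle, 1.64), vehicle mouse 2 (adipocytes, 0.995, and keratinocytes, 0.28), anti-PD-1 mouse 1 (keratinocytes, 0.41) and anti-PD-1 mouse 5 (red blood cells, 0.72).

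The interaction of ESK981 and anti-PD-1 was called for Scarna17 (3.12), Gm23547 (3.92), Gm15466 (1.64) and Gm23134 (−1.62), all among the 46 genes below that set vehicle apart, so a vehicle batch is not excluded for them.

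Other splits of the mice into groups of the same sizes were drawn 100 times per comparison, the real split included. For ESK981 against vehicle only the real split gave as many genes (2278, highest other 109) or as many lists (14, highest other 10). This argues against chance for both. For anti-PD-1 against vehicle 2 splits gave at least 124 genes (highest other 241, with vehicle 1 and anti-PD-1 1 to 4 against the rest). For the combination against vehicle 2 gave at least 96 (highest other 105, with vehicle mouse 5 and 4 combination mice on one side). Chance is less likely for these 2 counts but was not excluded, since a wrong grouping gave more genes in each. Against vehicle the real split also follows the flow cell, so a rare count does not separate treatment from batch. Chance was not excluded for the 1 list of the combination against vehicle (10 splits as large, highest other 14). The real counts of 0 were reached by all 100 splits: lists of anti-PD-1 (highest other 1), genes and lists of the combination against ESK981 (1219 and 11) and against anti-PD-1 (61 and 7), and lists of the interaction (3). The 1219 genes came from ESK981 mice 1 and 2 with combination mice 2, 3 and 5 against the rest, a structure of the samples that the treatment does not follow. For the 4 interaction genes 1 split was as large (highest other 1). Other splits mixed vehicle with anti-PD-1 mice, which adds the vehicle difference of these genes to the spread. They therefore could not exclude chance here.

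The 46 genes that set vehicle apart from every treated group placed vehicle 5R, which shared the flow cell of the treated tumours, at 1.08 on a scale from the treated mean (0) to the mean of the other vehicle tumours (1), anti-PD-1 4R at 0.918 and the other 22 treated tumours between −0.508 and 0.307. For depth, 4 treated tumours were sequenced within the range of the vehicle tumours. Their median position was 0.239, below the lowest vehicle tumour (0.882). ESK981 3R and combination 1R and 2R lay near the top of that range (1.78e+07 to 1.83e+07 fragments), at 0.131, 0.171 and 0.307. Vehicle 3L, at 1.84e+07 fragments, lay at 1.04. The shallowest was anti-PD-1 4R itself, and the 46 genes were picked for setting these groups apart, so depth was not excluded. This test replaced a fit with depth as a term, seen before. There the median absolute log2 fold change went from 1.63 to 1.28 and 0 of 46 calls were left, since depth and group overlap little. For ribosomal RNA carry-over, at least 105% of the median change was left in each of the 3 comparisons after its correction (mean over the comparisons 1.63 before, 1.78 after) and 29 of 46 genes were still called. Of the treated tumours only anti-PD-1 4R and combination 5R reached the ribosomal-RNA-like FPKM of the vehicle tumours (127087 or more). Carry-over and group thus also overlap little, and carry-over was not excluded. The flow cell test, which rests on 1 tumour, could not decide. Sequencing depth, ribosomal RNA carry-over, a library batch of the vehicle tumours and a wrong label on anti-PD-1 4R stay open. A library batch that vehicle 5R shared with the other vehicle tumours predicts the position of 5R. It predicts that of anti-PD-1 4R only if 4R was made in it, which cannot be told apart from a wrong label on 4R. These 2 tumours also share low depth, much mitochondrial RNA and a correlation of residuals of 0.72. A response common to all 3 treatments is a biological candidate that these groups do not separate from a vehicle batch.

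The lower interferon gamma, MHC and T cell genes of ESK981 tumours were set against 3 technical explanations. Scaling protein-coding genes to equal sums left the interferon gamma list at −1.66 (−1.56 before). For the vehicle library batch, ESK981 mice were compared with the other 2 treated groups. They differed from the mean of those groups by −1.18 ± 0.331 (exact permutation p = 0.003 over 3003 splits of 15 mice). No tumour labelled vehicle entered the difference or the permutation, but the SE used the spread of all 4 groups, vehicle included. Anti-PD-1 4R entered, whose label or batch is in doubt. Both other groups had received anti-PD-1 and lay mostly on other lanes, so this contrast cannot exclude a vehicle batch. Where only ESK981 differed, the list means were −0.41 with the combination and −0.34 with anti-PD-1. For fewer cells of every non-tumour type, the endothelial list was set against T cells, macrophages, dendritic cells and neutrophils in ESK981 minus vehicle. It stood above the mean of these 4 immune lists by 0.993 ± 0.138, which argues against an equal loss of these types only. Left out were regulatory T cells (−0.03 ± 0.14), B and plasma cells (−0.05 ± 0.42), NK cells (−0.41 ± 0.19) and mast cells (−0.63 ± 0.45). The fibroblast and matrix list was at −0.82 ± 0.31, so stroma in general was not shown to be spared. A lower immune infiltrate or interferon gamma signal with ESK981 alone remains a biological candidate that these tests did not settle. The hypothesis was found and tested on the same data. The fit with a flow cell term put the interferon gamma list at 0.25, an effect that rests on vehicle 5R. That tumour scored −1.87 in the list, and its mouse −1.19.

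Tumours of different mice with neighbouring library numbers resembled each other in places: ESK981 1R and 2R had a correlation of residuals of 0.888, the highest of the pairs compared, though on different lanes, while the 2 tumours of ESK981 mouse 1 were at −0.361, the lowest of the 13 same-mouse pairs. Over all pairs, neighbours of different mice exceeded the 2 tumours of a mouse by 0.0178 ± 0.151 (means 0.0603 and 0.0425, 13 pairs each), so labels of a neighbouring mouse cannot be told apart from true pairs here. Residuals within a group correlate negatively by construction, and all other pairs of different mice in a group were at −0.159 ± 0.0311 (n = 96). Those of them in 1 lane were at −0.168 ± 0.0408 (n = 54). These values cannot exclude a shared lane, since lane largely follows group and the group means were taken out of the residuals. A tumour can enter several pairs, so the pairs are not independent, though the SE given here treat them as such. No biological explanation was tested.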

How the results depend on the processing

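The fits without vehicle 5R, anti-PD-1 4R and combination 5R (the 3 libraries in doubt), without ESK981 1R and 2R, without combination 1L and with protein-coding genes scaled to equal sums are tests chosen after the data were seen, and the left-out libraries were picked from their profiles, so counts move partly by construction.

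Of 15 list results past the threshold, 298 of 343 values over the alternatives kept direction and side of the threshold, 39 were weaker and 6 reversed. Of 124 gene results, 2578 of 2951 kept both, 350 were weaker and 23 reversed. Of results not past it, 171 of 5701 list values and 75 of 2327 gene values became stronger, and 4 reversed; a change of sign while not called was not counted as a reversal. The correlation of the ESK981 effects ranged from 0.129 to 0.429 over settings and from 0.079 to 0.414 over left-out mice, against a jackknife SE of 0.305.

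Genes called for ESK981 against vehicle (2278) were 1412 with no filter, 4421 with median-of-ratios scaling, 4835 with quantile normalization, 5786 with the flow cell term, 6015 with array weights, 4796 without the 3 libraries in doubt, 1390 without ESK981 1R and 2R and 3674 with equal protein-coding sums. In the same order of settings, anti-PD-1 against vehicle (124) gave 56, 358, 432, 4397, 2762 and 1769, and 242 with equal protein-coding sums. The combination against vehicle (96) gave 54, 1048, 1236, 4467, 1675 and 1461, then 1003 with equal protein-coding sums and 167 with tumours and a mouse random effect. Against ESK981 the combination (0) gave 41 genes without the 3 libraries and 1 without combination 1L. Against anti-PD-1 (0) it gave 1 with no filter and 25 with array weights. The interaction (4) gave 1 with pseudocount 0.1, 0 with no filter, 61 with median-of-ratios, 118 with quantile normalization, 4033 with the flow cell term, 1767 with array weights, 1 without a mean-variance trend, 725 without the 3 libraries, 1 without ESK981 1R and 2R, 76 without combination 1L and 23 with equal protein-coding sums. Testing every gene without a filter enlarges the adjustment; for the other settings the cause was not tested.

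Lists passing for ESK981 against vehicle (14) were 6 with the flow cell term (5 higher and 1 lower, only 1 of them, the mitochondrially encoded RNA quality list, among the 14), 0 with camera and an estimated correlation and 24 with the preset correlation. For anti-PD-1 (0) they were 1 with median-of-ratios, 1 with quantile normalization, 5 with the flow cell term (4 higher, 1 lower) and 20 with the preset correlation. For the combination against vehicle (1) they were 0 with median-of-ratios, quantile normalization, array weights, without the 3 libraries, equal protein-coding sums, only the groups compared and the estimated correlation, 4 with the flow cell term (3 higher, 1 lower, none of them the 1 called before) and 10 with the preset correlation. For the combination against ESK981 (0) they were 11 with median-of-ratios, 11 with quantile normalization, 9 with array weights, 11 without the 3 libraries, 7 without combination 1L, 9 with equal protein-coding sums and 23 with the preset correlation. Against anti-PD-1 (0) there were 6 with the preset correlation. For the interaction (0) there were 9 with median-of-ratios, 10 with quantile normalization, 3 with the flow cell term (1 higher, 2 lower), 11 with array weights, 10 without the 3 libraries, 4 with equal protein-coding sums and 24 with the preset correlation. The cause was not tested.

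Leaving out 1 mouse gave 1054 to 2533 genes for ESK981 against vehicle (lowest without vehicle 2), 29 to 375 for anti-PD-1, 62 to 408 for the combination, 0 to 0 for the combination against ESK981, 0 to 59 against anti-PD-1 and 0 to 67 for the interaction, and 11 to 15, 0 to 0, 0 to 2, 0 to 10, 0 to 0 and 0 to 9 lists. The 4 interaction genes were 2 and 1 without vehicle 2 and 3, 0 without vehicle 4, 0, 1, 12, 0 and 0 without ESK981 1 to 5, 1, 1, 0, 29 and 35 without combination 1 to 5, 0 without anti-PD-1 1, 2 or 3, and 55 and 67 without anti-PD-1 4 and 5. Lists of the interaction were 6 without vehicle 5 and 9 without combination 5, and 2 lists passed for the combination against vehicle without combination 2. No paired analysis was possible because the mouse numbers were given within each group and tie no mice together.

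Reversals were with the flow cell term, except for Mki67. For ESK981 against vehicle the log2 fold changes became −0.54 for Mir6920, 0.54 for Cd3g, 0.55 for Cd3e, 0.12 for Trbc2, 0.60 for Lck, 0.40 for Nkg7, 0.16 for Lag3, 0.49 for Pdcd1, 0.44 for Ctla4, 0.53 for Msr1, 0.15 for Csf3r, 0.022 for Irf8, 0.0088 for Gbp2, 0.019 for Irf1, 0.012 for Socs1, 0.092 for Tap1, 0.80 for Cxcl9, 0.67 for Cxcl10, 0.34 for Ifng, 0.44 for Acod1, 0.0081 for Pdcd1lg2, 0.44 for Ciita and 0.41 for Nlrc5. The lists of T cells became 0.38, CD8 genes 0.14, inhibitory receptors 0.37, dendritic cells 0.23, interferon gamma 0.25 and MHC class I 0.08. For the combination against vehicle Cxcl9 became 1.95, Cd3e 1.56 and Pdcd1 1.33, called there. Without ESK981 1R and 2R, Mki67 became 0.74 against vehicle. The cause was not tested, though the flow cell effect rests by construction on vehicle 5R. Depth limits genes near 1 FPKM most in vehicle tumours, which had the fewest fragments.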

Other observations

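All tests of the genes below were chosen after the result was seen.

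Single genes outside the main results differed between ESK981 and vehicle tumours, and no theme was tested for them. The prolactin receptor Prlr rose from 9.49 ± 1.002 to 23.1 ± 7.59 FPKM (2.26-fold, adjusted p = 0.00381) and the cystine transporter Slc7a11 from 7.46 ± 2.62 to 16.8 ± 2.20 FPKM (2.31-fold, adjusted p = 0.0114). Others that rose were the endothelial cadherin Cdh5 (1.16 ± 0.475 to 3.04 ± 0.693 FPKM, 2.25-fold), the pericyte marker Rgs5 (2.08-fold), the matrix protein Mgp (25.4 ± 6.31 to 78.9 ± 53.9 FPKM, 2.40-fold), Sparcl1 (2.27-fold) and the caveolin Cav2 (2.19-fold), while the endothelial and pericyte lists did not pass (adjusted p = 0.249 and 0.983). Col1a1 fell from 106 ± 86.6 to 23.1 ± 4.36 FPKM (3.49-fold, adjusted p = 0.0108) and Col3a1 from 47.6 ± 49.0 to 8.62 ± 1.53 FPKM (3.37-fold, adjusted p = 0.0246), with an SD in vehicle mice close to the mean, and the fibroblast and matrix list did not pass (adjusted p = 0.0789).

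The complement component C3 fell from 25.6 ± 13.9 to 3.72 ± 1.66 FPKM (5.43-fold, adjusted p = 0.00266), the itaconate-producing enzyme Acod1 4.33-fold (adjusted p = 0.00924) and Pdcd1lg2, which encodes the second ligand of PD-1, from 4.32 ± 1.42 to 0.582 ± 0.535 FPKM (4.19-fold, adjusted p = 0.0056). Ciita and Nlrc5, which encode activators of MHC genes, fell 3.30- and 3.47-fold. Slc39a7, which lies in the MHC region (chromosome 17, 34028269 to 34031682), fell 2.77-fold against vehicle (adjusted p = 1.56e-05) and also 2.19-fold with anti-PD-1 and 2.73-fold with the combination, so it goes with the genes that set vehicle apart.

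The proliferation marker Mki67 was at 2.80 FPKM in ESK981 1R and 2.70 FPKM in ESK981 2R, against 25.9 to 36.1 FPKM in the other 6 ESK981 tumours, 1 of them from the mouse of 1R.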
